A study of Mus musculus with 6 samples.

How the data were processed

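Polyadenylated RNA from mouse bone marrow was made into stranded libraries, pooled and sequenced as paired ends, per the labels' protocols. There were 6 libraries, 3 labelled Gab2 +/+ (WT A, B and C) and 3 labelled Gab2 -/- (NULL A, B and C), and groups and letters were taken from the sample titles. The values are FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, as deposited by the authors. Bowtie, Cufflinks and the builds mm10 and GRCm38 are named in the submitters' processing notes, with no versions or roles. The gene annotation, any filter and any scaling between libraries are not given in the sources used here.

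Each library table held 23848 rows with a gene symbol and a value. The table of the whole series differed from the library tables in 0 values, so the library tables were used. Where a symbol stood on more than 1 row (256 symbols), the row with the highest mean was kept and 489 rows were left out. Symbols were matched to GENCODE vM21 on GRCm38, 21684 by name and 1269 by an older name, for positions, transcript lengths and GC content. Gene-level FPKM do not show which exons carry remaining reads. The 13 genes of the mitochondrial genome were not found among the gene symbols under the names searched, so that list was not tested. FPKM are not counts, so no count model was used.

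Depth was estimated from the most common step among low FPKM values, multiplied by the length of the longest annotated transcript less 150 bp. This gave about 54.32, 17.95 and 22.54 M fragments for WT A, B and C and 68.73, 23.25 and 39.93 M for NULL A, B and C, and these are approximations that support no counting interval. Small RNA genes, whose FPKM are inflated by short length, held between 5.99% (WT A) and 31.3% (WT C) of the summed FPKM, so a total of the FPKM is a poor measure of library size.

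Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 libraries, with empirical Bayes moderation along a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. For Gab2 an exact permutation test of FPKM was added. Gene lists with at least 3 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over 22 lists, and again with an estimated correlation and with fry. Camera asks whether members rank higher or lower than other genes, and the PValue of fry whether they move on balance in a single direction.

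Before the data were examined, 29 lists were fixed, covering GAB2 signalling partners, ERK, STAT5 and FOXO responses, immediate-early and dissociation stress, inflammation, interferon response, proliferation, MYC targets with ribosome biogenesis, markers of neutrophil (primary granule, and secondary granule and mature), monocyte and macrophage, dendritic, erythroid, megakaryocyte and platelet, mast cell and basophil, eosinophil, B, plasma, T and NK, stem and progenitor, stromal, endothelial, osteoclast and muscle cells, the mitochondrial genome, genes flanking Gab2, and sex-specific and strain-variable genes, the last pair as values without a list test. Some genes stand in more than 1 list. A further 10 lists were chosen after seeing the data. The genes named are Gab2, up to 12 genes in each direction with the largest absolute log2 change among called genes without overlap between the groups (leaving out predicted genes, pseudogenes, microRNAs and snoRNAs), and list members that passed the threshold, or otherwise those with the smallest p as values. Results of some single genes are not reported here.

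Alternatives planned before the data were examined were other pseudocounts, other filters on low values, quantile normalization, rescaling to a common total, median-of-ratios rescaling, no variance trend, robust moderation, array weights, a block on the replicate letter, other thresholds and leaving out each library. Alternatives leaving out small RNA genes, rescaling to a common total without them, using all rows of the table, testing against a log2 change of 0.5 and leaving WT C out of the estimated correlation were added after seeing the data. The limma steps were tested on simulated data for this comparison with 9916 genes, of which 200 in all were changed. The test recovered 50.7% of genes changed by 0.5, 95.5% of those changed by 1 and 95.5% of those changed by 2 on the log2 scale, and 6.40% of its calls were false. The simulation had independent noise for each gene, few changed genes with random signs and no shift shared by the genes of a library. Its shares therefore do not describe the real comparison, where most genes were called.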

Results

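RNA sequencing of mouse bone marrow was available for 3 libraries from Gab2 +/+ samples (WT) and 3 from Gab2 -/- samples (NULL). GAB2 is a scaffolding adaptor that carries signals from cytokine receptors and from the BCR-ABL1 oncoprotein to the phosphatase SHP2 and to phosphatidylinositol 3-kinase. The comparison asks which transcripts differ in the Gab2 -/- samples, in a series concerned with GAB2 signalling in myeloid and lymphoid transformation by BCR-ABL1. Expression was given as FPKM for 23359 gene symbols, of which 9916 had a mean of at least 1 FPKM and were tested. The most common step among low values placed the libraries at roughly 17.95 to 68.73 M fragments, M standing for a factor of 1000000, with WT B the shallowest and NULL A the deepest. The labels name no animals or cultures, so p-values measure only the spread between these samples, which may be technical.

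Gab2 itself was far lower in every NULL library. It lies on chromosome 7 from 97081586 to 97308946 on the plus strand of GRCm38 and is annotated as protein coding. The gene measured 2.95 ± 0.466 FPKM in WT (SD, n = 3) and 0.157 ± 0.0410 FPKM in NULL (SD, n = 3), so that NULL held 5.31% of the WT mean. The 3 WT libraries read 3.33, 3.10 and 2.43 FPKM and the 3 NULL libraries 0.123, 0.145 and 0.203 FPKM. The log2 change of FPKM + 1 was -1.77 (SE 0.104, limma adjusted p = 1.83e-05). An exact two-sided permutation test of the FPKM gave p = 0.1, the smallest that 3 libraries against 3 allow.

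In the NULL libraries all 31 proliferation genes and all 23 MYC target and ribosome-biogenesis genes fell on the deposited scale, with median log2 changes of -1.07 and -1.14 (adjusted p = 0.384 and adjusted p = 0.216 with an estimated correlation). Of 26 tested B-lineage genes 19 rose, as did 14 of 18 interferon-response genes and 13 of 17 FOXO-response genes (adjusted p = 0.216, 0.216 and 0.147 with an estimated correlation). Limma camera called these 5 lists with its preset correlation, but another division of the 6 libraries called as many lists in all as the real one, 11 each. That division still set unequal numbers of WT and NULL libraries against each other. It therefore does not measure how many lists would be called without a group difference. In the ERK response list, which was not called (camera adjusted p = 0.091), 6 of 8 genes fell, with the transcription factor Etv5 dropping from 14.9 to 1.43 FPKM.

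Across the transcriptome 6479 of 9916 genes (65.3%) passed the limma test at an adjusted p of 0.05, 2311 higher and 4168 lower in NULL. With a log2 change of at least 1 in addition, 391 were higher and 594 lower on the deposited scale, a balance that turned under 3 rescalings. It was 514 higher and 323 lower after median-of-ratios rescaling, 494 and 287 after quantile normalization and 854 and 274 after rescaling to a common total. The WT and NULL values did not overlap for 7045 genes (71.0%) on the deposited scale, against 10% by chance for libraries without a common offset. Median-of-ratios factors were 1.04 to 1.07 in WT and 0.928 to 0.960 in NULL. Such an offset between the groups adds to the share without overlap, which was not counted after rescaling. The direction of the calls depended on how libraries were scaled. Lower genes made up 64.3% of the calls on the deposited scale, 50.8% after median-of-ratios rescaling (3143 higher, 3242 lower), 53.7% after quantile normalization (2824 higher, 3278 lower) and 33.9% after rescaling to a common total (2010 higher, 1030 lower). The median log2 change of all tested genes was -0.13, 0.0098, -0.030 and 0.12 in these cases, so list medians on the deposited scale stand against -0.13.

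**Figure D1:**
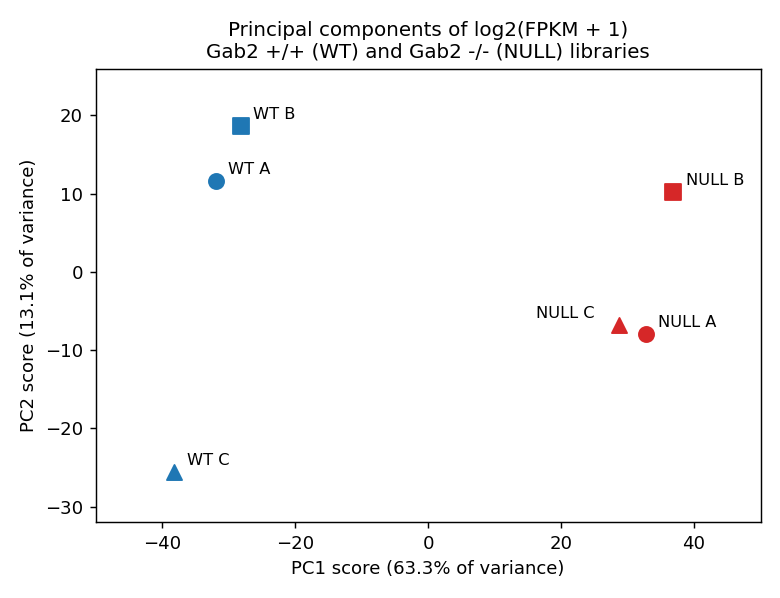
Scores of the 6 libraries on the leading principal components of log2(FPKM + 1) over 9916 genes, with PC1 (63.3% of the variance) on the horizontal axis and PC2 (13.1%) on the vertical axis; blue symbols are WT, red symbols NULL, and symbol shapes are replicates A, B and C. WT and NULL libraries lie on opposite sides of PC1, and WT C lies at -25.6 on PC2, away from WT A at 11.6 and WT B at 18.6.

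Libraries of a group resembled each other more than those of the other group. Pearson correlations across genes lay between 0.960 and 0.979 within groups and between 0.890 and 0.923 across groups. Genes are not independent replicates, so these values describe the libraries only. The median gene had an SD of 0.093 (WT) and 0.096 (NULL) on the log2 scale.

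Among the genes with the largest increases, Ramp3, which modifies the ligand specificity of calcitonin-family receptors, rose from 0.103 ± 0.0626 to 15.7 ± 0.258 FPKM (limma log2 change 3.92, SE 0.071). Il7r, the interleukin-7 receptor alpha chain needed for early B-cell growth, rose from 10.6 ± 4.96 to 75.8 ± 9.54 FPKM. The G-protein subunit Gng4 rose from 2.87 ± 0.669 to 36.3 ± 4.77 FPKM, the exchange factor Dock9 from 6.62 ± 2.49 to 51.8 ± 2.38 FPKM, and the guanylate-binding protein Gbp9 from 3.09 ± 1.97 to 26.5 ± 1.91 FPKM. Ly6f, Tmem59l, AA467197, Adprhl1, Grtp1 and the serine protease Htra3 also rose, by 2.81 to 3.56 on the log2 scale. Rnu11, the spliceosomal U11 RNA, was listed at 116.8, 0 and 0 FPKM in WT A, B and C and at 170.8, 205.8 and 146.3 FPKM in NULL. Its call was lost without several single libraries, with adjusted p-values up to 0.086.

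Of the genes with the largest decreases, Cd22, an inhibitory co-receptor of B cells, fell from 45.9 ± 23.1 to 1.74 ± 0.205 FPKM (limma log2 change -4.00, SE 0.284). WT C read 72.6 FPKM for Cd22 against 33.1 and 32.2 FPKM in WT A and B. Tmem119 fell from 17.98 ± 3.29 to 1.11 ± 0.400 FPKM, the intermediate filament gene Bfsp2 from 45.3 ± 14.5 to 4.37 ± 0.7005 FPKM, and Etv5 by 2.71 on the log2 scale. The palmitoyltransferase Zdhhc2, the cadherin Cdh17, the adhesion receptor Cd2, Rnase12, Trim12a and the proton channel Hvcn1 fell by between 2.19 and 2.80. Hbb-b1, a beta-globin gene with near-identical copies, was listed at 8.31, 7.21 and 58.7 FPKM in WT and at no more than 0.000359 FPKM in any NULL library. Its paralog Beta-s was listed at 2.16, 2.85 and 23.2 FPKM in WT and at no more than 0.0828 FPKM in NULL. Reads of these copies cannot be assigned with certainty. The log2 change of Beta-s was -2.69, and -1.76 without WT C. Its call was lost with a pseudocount of 5 (adjusted p = 0.051) and with robust moderation (adjusted p = 0.060). Beta-globin haplotypes differ between inbred strains, and the strain of the groups is not given in the sources used here.

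**Figure D2:**
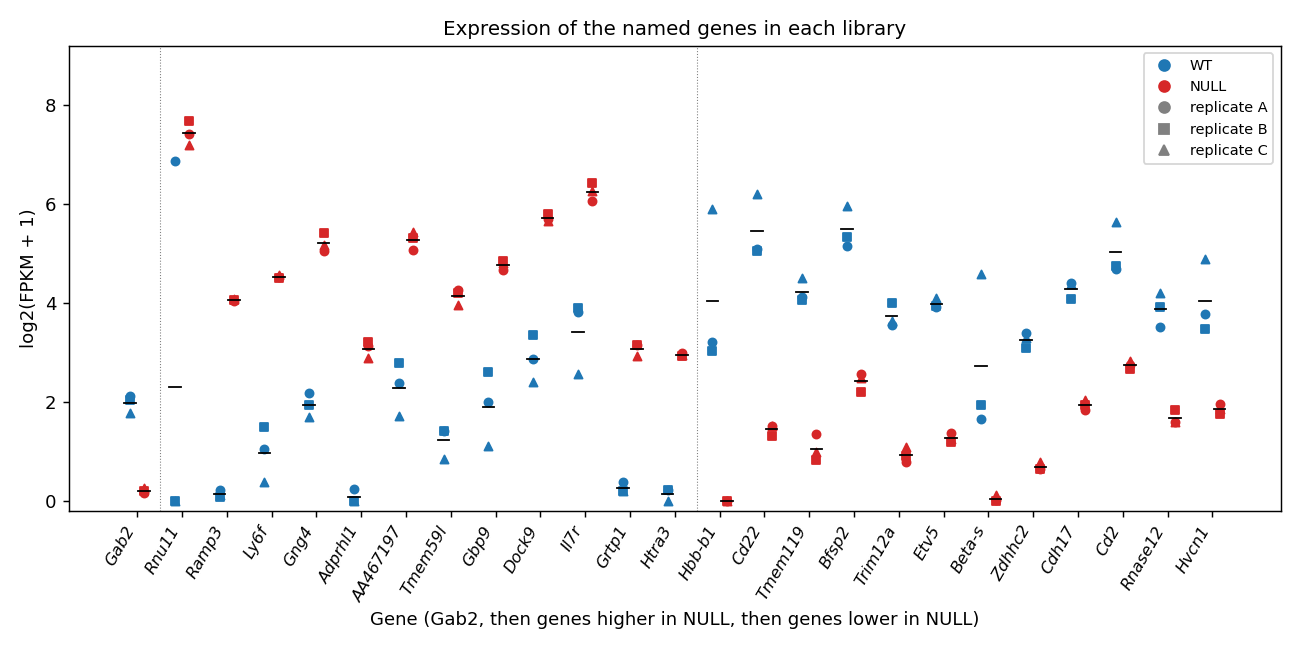
Expression of Gab2 and of the genes with the largest called increases and decreases, as log2(FPKM + 1) on the vertical axis, with genes along the horizontal axis; each point is a library (blue WT, red NULL, shapes for replicates A, B and C) and black bars are group means on this scale, n = 3 each. WT and NULL points do not overlap for any gene shown, Cd22 falls from 45.9 to 1.74 FPKM, and Rnu11 is at 0 FPKM in WT B and WT C.

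Proliferation genes fell without exception, 31 of 31, with limma camera giving an adjusted p of 6.81e-07 (adjusted p = 0.384 with an estimated correlation). The DNA clamp Pcna went from 446 ± 13.7 to 214 ± 36.5 FPKM, the topoisomerase Top2a from 332 ± 2.39 to 155 ± 27.5 FPKM and the ribonucleotide reductase subunit Rrm1 from 129 ± 2.25 to 46.2 ± 7.40 FPKM. The MYC target and ribosome-biogenesis list fell in 23 of 23 members (camera adjusted p = 3.93e-07, adjusted p = 0.216 with an estimated correlation). The nucleolar gene Npm1 dropped from 1801 ± 79.4 to 581 ± 34.7 FPKM, the chaperone Hspd1 from 313 ± 15.1 to 83.3 ± 7.50 FPKM and Odc1, which opens polyamine synthesis, from 118 ± 1.34 to 49.98 ± 4.36 FPKM. Both lists kept negative medians under every scaling tried, and 23 and 20 of their members were called lower in each of them.

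B-lineage genes rose in 19 of 26 tested members and fell in 3, with a median log2 change of 0.74 (camera adjusted p = 6.55e-06, adjusted p = 0.216 with an estimated correlation). Transcripts of early B-cell development were among those that rose. The terminal transferase Dntt went from 33.4 ± 16.6 to 161 ± 5.003 FPKM, the recombinase gene Rag1 from 1.02 ± 0.676 to 7.01 ± 0.0900 FPKM, the transcription factor Ebf1 from 53.3 ± 5.85 to 103 ± 4.87 FPKM and the adaptor Blnk from 71.6 ± 12.1 to 171 ± 4.12 FPKM. Cd22 and Btk were among those that fell, and but Btk was not called under any of the 4 rescalings and changed sign under 1. Pax5 read 53.9 ± 9.35 FPKM in WT and 58.5 ± 5.11 FPKM in NULL and was not called on the deposited scale, but was called higher under 2 rescalings.

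Targets repressed by phosphatidylinositol 3-kinase and AKT through FOXO factors rose in 13 of 17 cases and fell in 2 (median 0.61, camera adjusted p = 4.51e-05, adjusted p = 0.147 with an estimated correlation). Pik3ip1, an inhibitor of that kinase, went from 5.88 ± 0.176 to 18.7 ± 2.09 FPKM, Txnip from 20.4 ± 0.982 to 36.5 ± 0.586 FPKM and the cell-cycle inhibitor Cdkn1b from 10.8 ± 1.12 to 17.7 ± 1.70 FPKM. Cited2 and Bnip3 fell, the former without a call after rescaling to a common total (adjusted p = 0.055), and Bnip3 read 133 FPKM in WT C against 44.6 and 44.3 FPKM in WT A and B. In the ERK response list 6 of 8 members fell and 1 rose (median -0.69), but the list was not called (camera adjusted p = 0.091). It was called in 3 of 18 alternatives, namely quantile normalization and rescaling to a common total with and without small RNA genes (smallest adjusted p = 0.0195). The feedback inhibitors Dusp6, Spry1 and Spred1 fell by 0.90, 0.98 and 0.90 on the log2 scale and Dusp5 rose by 0.97. Myc fell by 0.48, but its call was lost under 3 of the 4 rescalings, with a change of -0.12 under the weakest. STAT5 response genes rose in 7 of 12 cases and fell in none (median 0.45, camera adjusted p = 0.00241, adjusted p = 0.147 with an estimated correlation). Among them the survival gene Bcl2l1 went from 10.7 ± 1.37 to 28.8 ± 2.001 FPKM, the kinase gene Pim1 from 59.7 ± 5.12 to 118 ± 12.3 FPKM and the feedback gene Socs3 from 2.24 ± 0.229 to 8.29 ± 0.186 FPKM.

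Of the genes for GAB2 signalling partners 12 of 28 rose and 1 fell (median 0.10, camera adjusted p = 0.00241, adjusted p = 0.216 with an estimated correlation). Under the 4 rescalings the number higher was between 8 and 26 and the median between 0.23 and 0.48, and 10 members changed sign under at least 1. The family members Gab1 and Gab3 rose from 0.280 ± 0.0336 to 2.98 ± 0.463 FPKM and from 0.990 ± 0.556 to 4.71 ± 0.560 FPKM. The kinase subunit Pik3cd went from 69.5 ± 5.96 to 147 ± 11.03 FPKM and the phospholipase Plcg1 from 17.6 ± 2.59 to 33.9 ± 0.836 FPKM. Ptpn11, which encodes SHP2, was lower by a log2 change of -0.33 on the deposited scale, with the call lost under 3 of the 4 rescalings and the sign turned under 1, and Grb2 was not called at 14.7 ± 0.818 and 13.1 ± 1.01 FPKM.

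Interferon-response genes rose in 14 of 18 tested members and fell in 2 (median 0.93, camera adjusted p = 3.24e-06, adjusted p = 0.216 with an estimated correlation). Zbp1 went from 2.25 ± 1.28 to 10.9 ± 2.63 FPKM and Irf9 from 6.16 ± 0.279 to 14.2 ± 0.529 FPKM, while Bst2 fell from 10.6 ± 2.78 to 5.14 ± 0.827 FPKM. The inflammation list rose in 7 of 9 members and fell in 1 (median 0.69, camera adjusted p = 0.00208, adjusted p = 0.147 with an estimated correlation), with Tnfaip3 going from 3.47 ± 0.547 to 13.1 ± 0.674 FPKM and Tnf falling from 34.8 ± 3.63 to 16.3 ± 1.65 FPKM. Immediate-early and dissociation-stress genes rose in 7 of 12 cases and fell in 2 (median 0.73, camera adjusted p = 0.00253, adjusted p = 0.147 with an estimated correlation), led by Jun, Nr4a1 and Btg2 with log2 changes of 1.88, 1.84 and 1.96. Among the members counted as lower, Ifit2 of the interferon list and Dnajb1 of the immediate-early list changed sign under 2 and 3 of the 4 rescalings, and Dnajb1 was not called without WT C.

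**Figure D3:**
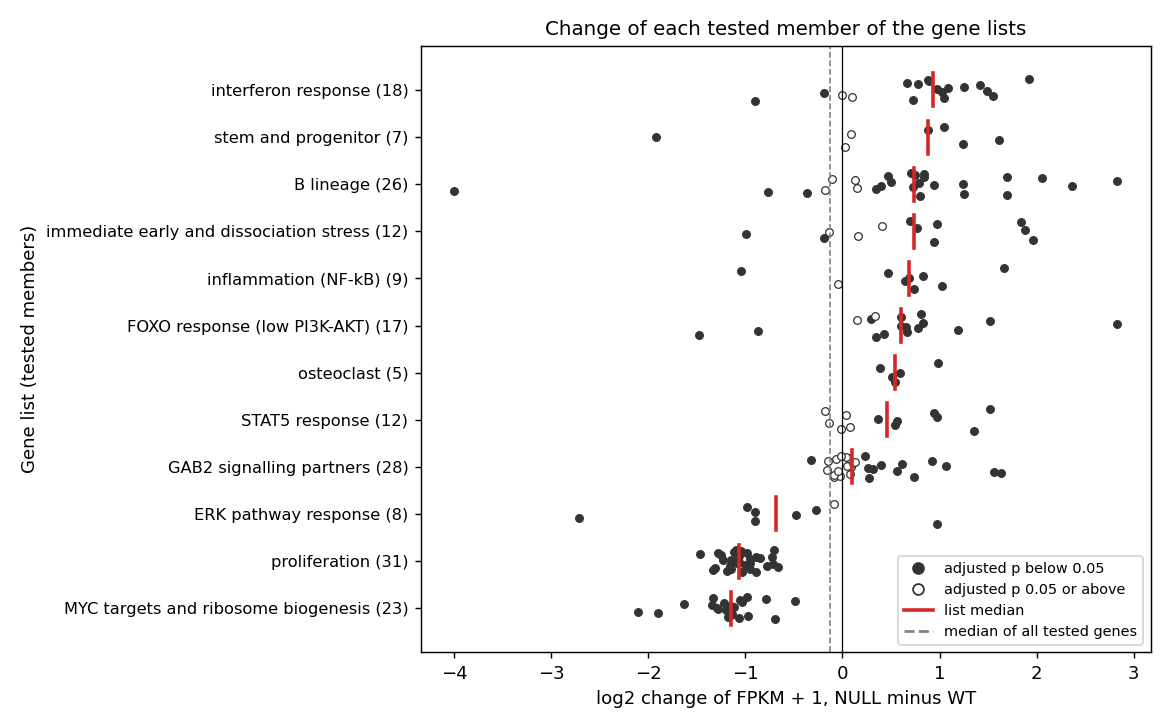
Log2 change of FPKM + 1 (NULL minus WT, horizontal axis) of each tested member of the 11 called gene lists and the ERK response list (vertical axis, with the number of tested members); filled points have an adjusted p below 0.05, open points do not, red bars are list medians and the dashed line is the median of all tested genes. The proliferation and MYC target lists lie wholly below 0 with medians of -1.07 and -1.14, and the interferon response list has a median of 0.93.

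Markers of other marrow cell types were mostly close to 0 in both groups. Mpo, Elane, S100a8 and S100a9, abundant in granulocytes, and Cd3e of T cells had means of at most 0.0112 FPKM, while the B-lineage genes had a median of 47.5 FPKM in WT and 82.1 FPKM in NULL. Only 2 of 28 monocyte and macrophage genes, 2 of 14 eosinophil genes, 1 of 26 mast cell and basophil genes and 2 of 15 muscle genes reached the expression filter, too few for a list test. The osteoclast list (5 of 5 higher, camera adjusted p = 0.00241, 0.147 as the adjusted p with an estimated correlation) consisted of Tcirg1, Clcn7, Ostm1, Nfatc1 and Acp5, the leading 3 of which serve lysosomes in many cells. In the stem and progenitor list 4 of 7 rose and 1 fell (camera adjusted p = 0.030, 0.216 as the adjusted p with an estimated correlation), with Erg and Myb also expressed in B-cell precursors. This call was lost in 4 of 18 alternatives, namely median-of-ratios rescaling (adjusted p = 0.056), both rescalings to a common total (largest adjusted p = 0.167) and leaving out WT C (adjusted p = 0.082).

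The remaining lists were not called by camera in the main analysis. These were plasma cell genes (1 higher and 4 lower of 9), T and NK cell genes (4 and 2 of 6), dendritic cell genes (2 and 2 of 6), erythroid genes (0 and 3 of 6), neutrophil primary granule genes (1 and 2 of 3), neutrophil secondary granule and mature genes (3 and 1 of 4), megakaryocyte and platelet genes (1 and 1 of 3), stroma, bone and adipocyte genes (0 and 3 of 3) and endothelial genes (2 and 1 of 3). The balance of the plasma cell genes turned to 5 higher and 3 lower after quantile normalization (median 0.25 against -0.20) and to 4 and 2 after rescaling to a common total without small RNA genes, with 4 members changing sign under at least 1 rescaling and 1 called in the opposite direction. Among the 18 alternatives with the preset correlation camera called the stroma, bone and adipocyte list in 5 (smallest adjusted p = 0.00347) and the T and NK cell list in 2 (0.0119). It called the neutrophil secondary granule (0.000398), erythroid (0.000187) and megakaryocyte (0.000669) lists in 1 each. Of the T and NK cell genes the adaptor Lat rose from 20.6 ± 0.812 to 96.4 ± 4.57 FPKM, and Cd2 and Thy1 fell. The medians of the dendritic and megakaryocyte lists were negative where their means and camera directions were positive. Among 20 tested genes flanking Gab2 on chromosome 7, 2 were higher and 9 lower (camera adjusted p = 0.263), with Alg8 falling from 17.5 ± 0.365 to 3.96 ± 0.252 FPKM. That balance was 1 and 4 after rescaling to a common total and 6 and 5 after the same without small RNA genes (median 0.043), and 6 of these genes changed sign under at least 1 rescaling.

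In total 11 of the 22 testable lists were called by camera with its preset correlation, 9 higher and 2 lower. With an estimated correlation 0 were called, and 5 had an unadjusted p below 0.05. The p-values rose even where the estimated correlation was close to or below the preset 0.01. For the STAT5 list (0.0105) the unadjusted camera p went from 0.00098 to 0.030, and for the FOXO list (-0.016) from 1.02e-05 to 0.0089. For the immediate-early list (-0.0054) it went from 0.0011 to 0.027. In these lists the rise therefore came from the form of the test rather than from a larger correlation. The loss of calls does not show that correlation between genes explains them. The adjusted p-values with an estimated correlation given above carry the same limit. Other divisions of the 6 libraries into 3 and 3 called up to 11 lists with the preset correlation, and at most 2 genes. They mixed WT and NULL libraries in unequal numbers. Part of the group difference thus stayed in their contrasts and part entered their spread. Counts of members adjusted over the list alone equalled those above except for the GAB2 signalling partners (11 higher) and the immediate-early genes (8 higher).

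Xist, transcribed from the inactive X chromosome, had means of 0.0113 FPKM in WT and 0.0193 FPKM in NULL, and the Y-linked Eif2s3y was at 45.2 ± 1.80 FPKM in WT and 34.6 ± 2.48 FPKM in NULL. Of 7 tested genes known to vary between inbred strains 2 were higher (Nnt, Wdfy1) and 4 lower (Trim12a, Ide, Glo1, Trim30d) in NULL. Ide, the insulin-degrading enzyme, went from 95.8 ± 2.40 to 27.3 ± 3.06 FPKM.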

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

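The alternatives without small RNA genes, with a common total without small RNA genes, with all rows, with a test against a log2 change of 0.5 and with an estimated correlation without WT C were chosen only after the data were seen. Gab2 kept its direction and its call under all alternatives in which it was tested, with log2 changes from -3.57 (pseudocount 0.1) to -0.62 (pseudocount 5) and adjusted p-values no higher than 0.000230, and it did not reach the stricter filter of 5 FPKM. With libraries left out in turn, 5825 to 6488 genes were called, and 10 or 11 lists. The stricter filter left 7067 tested genes, of which 1364 were called higher and 3495 lower. Lower genes made up 58.3% of the calls with no filter, 64.3% with the main filter and 71.9% with the stricter filter. The direction of the calls thus depended on abundance, and fewer tests alone do not account for the drop in higher genes. Rescaling to a common total left 3040 calls (1030 lower), and the same rescaling without small RNA genes gave 4456 higher and 2050 lower. In the former limma's prior degrees of freedom were infinite, so each gene took its variance from the trend alone. In the latter their median was 4.48. These fits differ only in the total used, so the small RNA genes in the total account for this and for the fewer calls. With small RNA genes the summed FPKM ran from 378472 (WT A) to 582975 (WT C) within WT. A log2 change of at least 1 left 985 genes (391 higher, 594 lower), and a test against a log2 change of 0.5 called 1838 (602 higher, 1236 lower), both by their stricter limits and on the deposited scale. With the limit of 1 more genes were higher than lower under 3 rescalings, 514 and 323 (median of ratios), 494 and 287 (quantile) and 854 and 274 (common total), and the test against 0.5 was not run on those scales. Of the 6479 calls, 85.7% kept their direction and call after median-of-ratios rescaling and 45.0% after rescaling to a common total, and quantile normalization called 25 of them in the opposite direction. Camera with an estimated correlation called 0 of 22 lists, and 0 without WT C, while fry, which does not compare a list with other genes, called 22. Over single named genes, 441 of 450 values under alternatives kept their call and 9 lost it, all of Rnu11 or Beta-s, and none reversed; of 459 list values 409 kept their side of the threshold, 26 lost a call and 24 gained it. Camera has no robust option, so that alternative was not run for lists, and the table of the whole series was no alternative since its values were equal. The letters are not stated to pair the samples, and deviations from the group means correlated by 0.073, 0.36 and 0.13 for A, B and C, although 6 of 6 libraries correlated best with their own letter. With the letter as a block 5844 genes (2050 higher, 3794 lower) and 12 lists were called.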

Other observations

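The tests of scaling for the proliferation and MYC target genes, of genes beside Gab2 and of the depth of WT C were chosen only after the result was seen. The 10 gene groups of the first 2 paragraphs were likewise chosen after seeing the data. Among them, genes of MHC class I antigen presentation stood out, with 16 of 16 tested members higher in NULL (median log2 change 1.43, camera adjusted p = 3.07e-11, adjusted p = 0.142 with an estimated correlation). H2-K1 went from 152 ± 13.1 to 410 ± 10.5 FPKM, H2-D1 from 156 ± 13.4 to 379 ± 25.6 FPKM and B2m, which is encoded outside the MHC, from 750 ± 39.8 to 1417 ± 89.98 FPKM. The list median lay between 1.43 and 1.82 on the deposited scale and under the 4 rescalings. H2 genes differ between inbred strains and H2-Q genes have near-identical copies, and the strain of the groups is not given in the sources used here, so a difference in strain stays open for the values of this list. Lysosomal genes rose in 11 of 22 cases and fell in 4 on the deposited scale (adjusted p = 0.354 with an estimated correlation), against 11 to 16 higher and 1 or 2 lower under the 4 rescalings, with 5 members changing sign under at least 1, and with Ctsb going from 18.5 ± 1.31 to 65.6 ± 3.65 FPKM.

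Further groups had more lower than higher members on the deposited scale, by numbers that depended on the scaling. Serine and one-carbon genes fell in 14 of 14 cases (median -1.32), with Asns going from 55.9 ± 8.54 to 16.02 ± 2.30 FPKM, and the CCT chaperonin in 8 of 8 (median -1.06), cytosolic aminoacyl-tRNA synthetases in 20 of 20 (median -0.82), proteasome genes in 33 of 37 with 2 higher (median -0.74), nuclear respiratory chain genes in 62 of 72 (median -0.72) and cholesterol synthesis genes in 14 of 19 (median -0.53). Glycolysis genes fell in 15 of 17 cases and 1, Hk1, rose (median -1.40). Cytosolic ribosomal proteins fell in 51 of 81 cases with 1 higher (median -0.47). The medians of these lists kept their sign under the 4 rescalings, while 19 ribosomal protein, 16 respiratory chain, 3 synthetase, 3 proteasome and 3 cholesterol synthesis genes changed sign under at least 1. Median-of-ratios rescaling left 40 ribosomal protein genes lower (2 higher), 58 respiratory chain, 17 synthetase, 32 proteasome (2 higher) and 13 cholesterol synthesis genes. After rescaling to a common total 9 ribosomal protein genes were lower (2 higher), 12 respiratory chain, 4 synthetase, 8 proteasome (2 higher) and 3 cholesterol synthesis genes. Without small RNA genes in that total 21 ribosomal protein genes were lower (9 higher), 48 respiratory chain (1 higher), 13 synthetase, 26 proteasome (4 higher) and 8 cholesterol synthesis genes (2 higher). The low counts of the common total thus belonged to the total with small RNA genes. Quantile normalization left 21 ribosomal protein genes lower (9 higher), 40 respiratory chain genes (3 higher), 15 synthetases, 26 proteasome genes (3 higher) and 11 cholesterol synthesis genes (1 higher). Serine and one-carbon genes, the chaperonin and glycolysis genes kept at least 10, 7 and 13 lower under each of the 4. The adjusted p with an estimated correlation was 0.174 for cholesterol synthesis, 0.570 for glycolysis, 0.573 for ribosomal proteins and 0.354 for the other lists of this paragraph.

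Proliferation and MYC target genes were lower in NULL, with a median log2 change of -1.10 over 54 genes, all below 0. A trend with transcript length and GC content and a trend with abundance were each argued against as the whole cause. The median stayed at -0.96 after removing the length and GC trend of the other genes and at -0.75 after removing the abundance trend, with upper quartiles of -0.80 and -0.58. After median-of-ratios rescaling it was -0.94 (upper quartile -0.80), against 0.0098 for all tested genes. That rescaling moved the all-gene median by only 0.14. An offset of that size was too small to give the fall, and a larger shift shared by all genes was not tested by it. The change was smaller under other rescalings, at weakest -0.68 for proliferation (quantile normalization) and -0.79 for MYC target genes (common total without small RNA genes). A hypothesis is that cells lacking Gab2 cycled and grew less. A different strain background, mix of cells, handling, growth state, or any culture or transformation of the cells cannot be separated from genotype in this design and was not tested. Mpo, Elane, S100a8 and S100a9 of granulocytes and Cd3e of T cells were near 0 FPKM in both groups, although the labels name bone marrow as the tissue. List medians in WT and NULL were 47.5 and 82.1 FPKM for B-lineage genes. They were 0 and 0.0046 FPKM for neutrophil secondary granule and mature genes, 0.026 and 0.012 for erythroid genes and 0.039 and 0.052 for monocyte and macrophage genes. These values argue against a whole-marrow mix of cells and for mostly B-lineage cells in both groups. Whether the cells were fresh, cultured or transformed by BCR-ABL1 stays open, since the labels used here name no cultures.

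Genes beside Gab2 included strong changes, such as Alg8 with a log2 change of -1.90 and Tenm4 with 0.79, which may point to sequence carried along with the targeted allele. Within 2.5 Mb of Gab2, 10 of 17 tested genes were called, 9 lower and 1 higher. Their median absolute change from the all-gene median was 0.30, and 69.8% of 9435 stretches of as many neighbouring tested genes were as large or larger. By this measure the stretch as a whole did not stand out, while single genes such as Alg8 stay open. The test did not reach beyond 2.5 Mb. Of the genes with the largest decreases, Beta-s, Trim12a and Cd22 also lie on chromosome 7, starting at 103826534, 104299894 and 30865402, and were not covered. Hbb-b1, the paralog of Beta-s, had no position in the annotation used and could not be placed.

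WT C stood apart from WT A and B in glycolysis genes, with a median log2 difference of 0.92 over 17 genes, all above 0. Lower sequencing depth is argued against, since WT B, the shallower library, differed from WT A by a median of 0.13. After median-of-ratios rescaling the difference of WT C was 0.89. The factors of WT A, B and C were 1.04, 1.06 and 1.07, so the offset they measure was too small to give or remove it. Slc2a1 read 25.1 FPKM in WT C against 7.34 and 8.84 FPKM in WT A and B. A difference in oxygen or handling of that sample may be considered as a hypothesis, and nothing in the labels tests it. Without WT C the glycolysis median was -1.09.

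The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 6479 genes and 1 of the 10 splits gave as many, the highest of the others being 2. For lists the real division called 11 and 2 of the 10 splits gave as many, the highest of the others being 11. That other division set WT A, NULL A and NULL B against WT B, WT C and NULL C. Every division but the real one held WT and NULL libraries on both sides in unequal numbers. Part of the group difference thus stayed in its contrast, where it can call lists, and part entered its spread, which lowers the gene calls. The counts therefore do not show what would be called without a group difference.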
